A study of Homo sapiens with 2 samples.

How the data were processed

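Gene expression was measured in KU812, an established cell line from a patient with chronic myeloid leukaemia (CML) that has features of basophils and their precursors. Cells had been transduced, with polybrene at 7 µg/mL, with a random control short hairpin RNA (shRNA) or with an shRNA against CD25, the alpha chain of the interleukin-2 receptor, and selected with puromycin at 2 µg/mL. Per the labels' labelling protocol, 100 ng of total RNA was amplified and labelled by a whole-transcript kit for Affymetrix arrays, while the extraction protocol names a larger amount as used for the arrays. Each group held 1 array, so the series has 2 arrays and no replicates. Groups were taken from the sample titles.

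The deposited table holds 1 log2 signal per probe set and array, for 53617 probe sets. The submitters' processing notes name RMA (robust multi-array average: background correction, quantile normalization and a summary over the probes of a probe set) and Affymetrix Expression Console 1.3.1.187. The log2 scale was read from the deposited values, which ran from 1.48 to 14.3 on the control shRNA array and from 1.54 to 14.4 on the CD25 shRNA array, with medians of 5.15 on both. Quantile normalization makes the distributions of the arrays alike, so a change shared by most genes would not show. Which arrays were normalized together, and any detection call per probe set, are not given in the sources used here. The number of arrays limits the precision of every value.

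Probe sets were named from a table of the platform's annotation, which gave 1 gene symbol for 16098 probe sets (30.0%) and several symbols for 0. The other 37519 probe sets are unnamed here. All 16098 Entrez identifiers were found in a RefSeq gene table of assembly GRCh38.p14, which was used only for current symbols, chromosome membership and gene order, as the genome build of the arrays is not given in the sources used here. The named probe sets covered 14884 genes, of which 779 had more than 1 probe set. Each gene was represented by its probe set with the highest mean signal. Genes with a log2 signal of 5 or more on at least 1 array were analysed, which left 10963 genes. IL2RA, which encodes CD25, was named for 0 probe sets, so the planned check of the targeted transcript could not be made.

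The difference between arrays was the log2 signal with CD25 shRNA minus that with control shRNA, and folds are 2 raised to its size. With 1 array per group no test was run and no p-value is given. Genes were counted by a fixed rule of size, 2-fold or more. Each difference was also ranked among those of the 500 genes nearest in mean signal, and this percentile describes these 2 arrays only. Before the data were examined, 32 gene lists were fixed, among them markers of basophils and mast cells, eosinophils, erythroid cells, megakaryocytes, neutrophils and monocytes, and lymphocytes. The median difference of each list with 5 or more measured members was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. A list was set apart when it lay outside the central 95% (below percentile 2.5 or above 97.5). Genes of a list are not independent of each other, so this is a description of the arrays and not a test of the conditions. Chromosomes were handled in the same way. Many members of the lists were unnamed here, and each list is given with its measured number.

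The genes named in the text follow a rule fixed at the same time. It takes the 12 genes with the largest positive and the 12 with the largest negative difference, leaving out small RNAs, clone names and antigen receptor segments; 1 of the genes it takes is not reported here. It then takes up to 4 members with the largest difference from each list, and all measured members of the interleukin-2 receptor and JAK-STAT lists. Alternatives changed the normalization, the filter on low signals, the size rule, the choice of probe set, the use of unnamed probe sets, the matching of random lists and the list summary.

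The procedure was tested on simulated arrays of the same 10963 genes, with noise of the spread seen between the 2 arrays (robust SD 0.27 on the log2 scale). Of 50 genes per size, the 2-fold rule picked 0 shifted by 0.5, 29 shifted by 1, 49 shifted by 1.5 and 50 shifted by 2 on the log2 scale. It picked 2 of 10643 unchanged genes. Lists of 20 genes shifted by 0.3 were set apart in 6 of 6 cases, and 5 of 100 unshifted lists were. The simulated noise was independent between genes and had the same spread at every signal. The real differences reached 0.69 at their 97.5th percentile, and members of real lists are not independent. These counts therefore do not give the rate of false calls on the real arrays. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.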

Results

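The expression profiles of KU812 cells carrying a control shRNA and of KU812 cells carrying an shRNA against CD25 were compared on 2 whole-transcript arrays, 1 per culture. The comparison addresses which transcripts differ in this CML cell line when CD25 is depleted. The labels describe the control culture as CD25 positive and the culture with CD25 shRNA as CD25 negative. The transcript of IL2RA itself was not analysed here, because no named probe set carried that symbol, so the labels were not checked at the RNA level. Across the 10963 genes analysed, the signals of the arrays had a Pearson correlation of 0.975 across genes, which are not independent replicates. The median difference was -0.03 on the log2 scale, and 95% of the differences lay between -0.68 and 0.69. With 1 array per group, none of the differences below has a replicate check.

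With CD25 shRNA, 112 genes had a signal at least 2-fold higher and 72 genes a signal at least 2-fold lower than with control shRNA, together 1.68% of the genes analysed. The balance towards higher signals held with some other rules but not with all. By 3-fold or more, 29 genes were higher and 10 lower. By 1.5-fold or more, 409 genes were higher and 417 lower. Over all probe sets, named or not, 465 were higher and 506 lower by 2-fold or more, and the unnamed ones held 341 and 424 of these. A difference of 4-fold or more was seen for 11 higher and 3 lower genes. Among the higher genes, 92 were protein-coding, 7 were long non-coding RNAs and 4 were microRNA genes. Among the lower genes these numbers were 59, 3 and 9. For 33 of the 112 higher genes the control signal was under the level minimum of 5 and for 37 it was 6 or more, and for 14 of the lower genes the signal with CD25 shRNA was under it. The size of such folds is the least certain. As the median of all probe sets was 5.15 and no detection call was used, control signals just above 5 are not known to lie above background either. Of the 484 genes with several probe sets at the level minimum, 14 had a probe set past 2-fold. In 12 of these all probe sets pointed the same way, and in 6 all were past 2-fold. A pair of probe sets of the same gene differed by a median of 0.15 on the log2 scale.

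The 4 genes furthest above control were DAZ2, DAZ3, DAZ1 and USP26. DAZ1, DAZ2 and DAZ3, near-identical Y-linked genes for germ cell RNA-binding proteins, were 19.5-fold, 23.2-fold and 22.7-fold higher with CD25 shRNA. Their probes can share transcripts, so these genes count as 1 observation. Their control signals, from 5.33 to 5.40, were close to the median of all probe sets, so the size of these folds is uncertain. USP26, an X-linked deubiquitinase gene known from testis, was 15.6-fold higher, at a log2 signal of 5.43 with control shRNA and 9.39 with CD25 shRNA. ZFP42, a pluripotency marker also called REX1, was 5.49-fold higher from a low control signal of 3.97. DSCR8, a long non-coding RNA gene, was 5.11-fold higher. IGFBP7, which encodes a secreted protein that binds insulin-like growth factors, was 8.41-fold higher from a control signal of 5.52. IGF1, which encodes such a growth factor, was 5.77-fold higher, at 7.36 with control shRNA and 9.88 with CD25 shRNA. FSTL5 was 4.39-fold higher and HEPH, which encodes the copper-dependent ferroxidase hephaestin, 4.01-fold. CXADRP3, a pseudogene whose signal cannot be told from that of its parent gene, was 3.99-fold higher. The control signals of DSCR8, FSTL5 and CXADRP3, 5.21, 5.05 and 5.26, were also close to the median of all probe sets, so these folds are uncertain. All 11 genes named here as furthest above control lay at or above percentile 99.8 of the 500 genes nearest in mean signal. As they were chosen for the size of their difference, this rank follows largely from the choice.

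The 12 genes furthest below control included 2 members of the basophil and mast cell list, CPA3 and SIGLEC6. CPA3, which encodes the granule protease carboxypeptidase A3, was 4.84-fold lower with CD25 shRNA, with log2 signals of 11.03 in control and 8.76. SIGLEC6, a sialic acid-binding receptor gene of mast cells, was 3.74-fold lower. IL1RL1, which encodes the receptor of interleukin-33, was 2.90-fold lower. CYTL1, a cytokine-like gene first found in CD34-positive cells, had the largest difference, 5.73-fold lower. CDK15 was 4.14-fold lower, CRISP3 3.63-fold, and HEY1, a transcription factor gene downstream of Notch, 3.59-fold. SLAMF6 was 3.47-fold lower, GPR65, an acid-sensing receptor gene, 3.32-fold, and CXCL10, an interferon-induced chemokine gene, 3.20-fold. The signals of CDK15, SLAMF6 and CXCL10 with CD25 shRNA, 4.81, 4.36 and 4.17, were under the level minimum, so the size of these folds is uncertain. That of CYTL1 with CD25 shRNA, 5.07, lay below the median of all probe sets, 5.15, so its fold is uncertain too. SNAI2, which encodes a zinc finger repressor, was 2.82-fold lower, and CA2, the gene of carbonic anhydrase 2, was 2.79-fold lower. A further probe set of GPR65 gave a difference of -1.34 beside the -1.73 used here. Each of the 12 lay below all 500 genes nearest in mean signal, which follows largely from their choice by size.

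**Figure D1:**
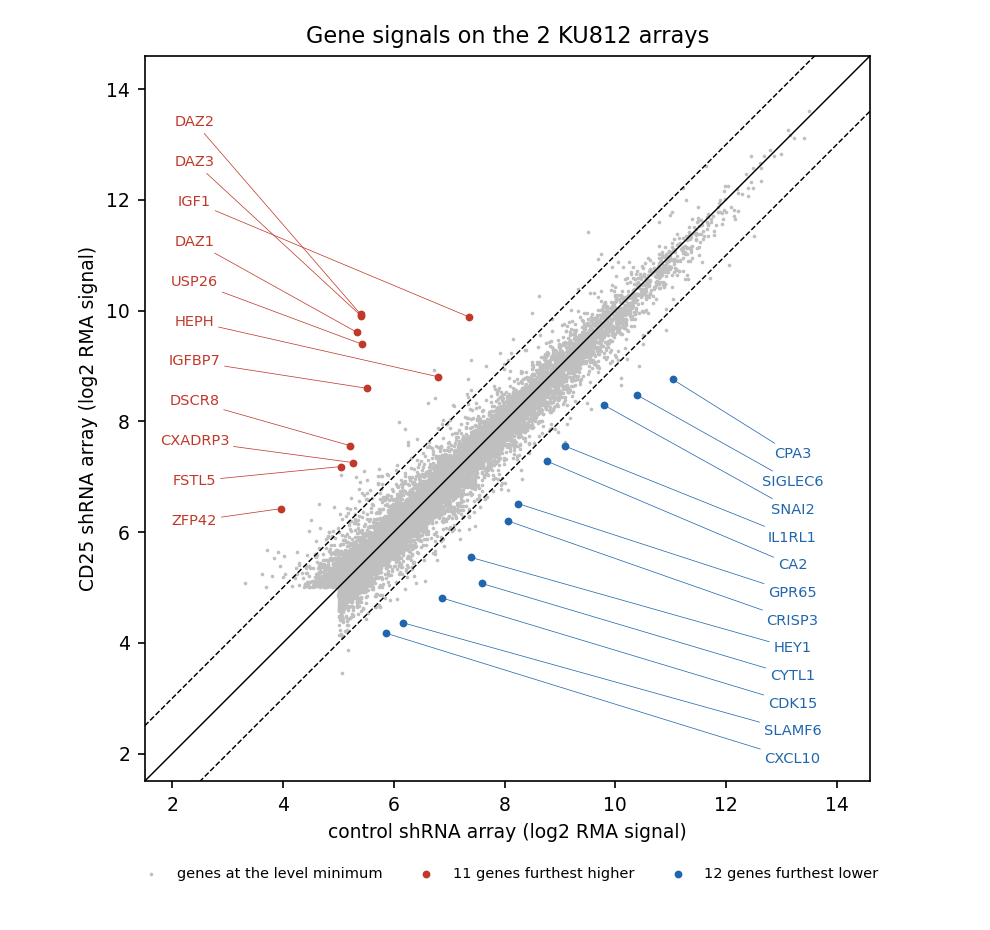
Log2 RMA signal of each of the 10963 genes on the control shRNA array (x axis) and the CD25 shRNA array (y axis), with the line of equality and dashed lines at 2-fold. Of the genes furthest higher 11 (red) and of those furthest lower 12 (blue) are named; DAZ1, DAZ2, DAZ3 and USP26 stand together at a log2 signal near 5.4 in control and above 9 with CD25 shRNA.

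As a list, basophil and mast cell markers were lower with CD25 shRNA. The median difference of the 21 measured members was -0.40 on the log2 scale (1.32-fold lower), below all 10000 random lists matched on mean signal, and 16 of the 21 had a negative difference. The size of this median depended on the level minimum: it was -0.68 over 17 members at a minimum of 6 and -0.95 over 13 members at 7. Of the members, 5 were at least 2-fold lower and 0 at least 2-fold higher. Besides CPA3 and SIGLEC6 these were KIT, the receptor of stem cell factor, 2.25-fold lower from a log2 signal of 12.5, ALOX5AP, which acts in leukotriene synthesis, 2.13-fold lower, and the tryptase gene TPSAB1, 2.13-fold lower. TPSAB1 falls outside the naming rule and was named after its value was seen, and its probes can share transcripts with other tryptase genes. In the 2 measured eosinophil markers, EPX and CLC, the differences were -0.43 and -0.31. Cajal body RNAs, whose yield can depend on RNA handling, were higher on the same array, with a median difference of 0.35.

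The other lineage lists were not set apart with the settings used here. The median difference was -0.03 for 15 erythroid genes, -0.20 for 11 megakaryocyte genes, 0.07 for 11 neutrophil and monocyte genes and 0.02 for 14 lymphocyte genes, at percentiles 65.6, 4.04, 81.6 and 62.2. The mean of the lymphocyte genes, -0.03, differs in sign from their median. The megakaryocyte list was set apart on the lower side in 3 of 12 alternatives, at percentile 2.44 without a level minimum, but its mean was -0.08. Over the alternatives its value ran from -0.21 to -0.02. That of the erythroid genes ran from -0.16 to -0.01, of the neutrophil and monocyte genes from -0.02 to 0.11 and of the lymphocyte genes from -0.21 to 0.06. Members of each list differed in direction. In the erythroid list CA2 was the 1 gene past 2-fold, EPB42, a red cell membrane protein gene, was at -0.55 and GATA1, the erythroid transcription factor gene, at 0.50. The globin genes were not analysed here. In the neutrophil and monocyte list LYZ, the lysozyme gene, was higher by 1.14 on the log2 scale. Among the megakaryocyte genes, of which 7 were negative, THBS1 was at 0.71, GP9 at -0.52, FLI1 at -0.44 and PLEK at -0.42. Among the lymphocyte genes CD4 and CD7 were at -0.72 and -0.69, and PRF1 and CD8A at 0.69 and 0.52. Surface markers used for CML stem cells and progenitors had a median difference of -0.03 over 11 members, at percentile 59.6, with 8 of the 11 negative. KIT, also counted in the basophil and mast cell list, was the 1 member past 2-fold, 2.25-fold lower. IL1RAP, the interleukin-1 receptor accessory protein gene, was 1.95-fold lower, CD44 was at -0.56 and CXCR4 at 0.58. The surface marker list was set apart on the lower side with a level minimum of 7, at -0.52 over 7 members, and by its mean, -0.24.

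The genes of the pathway around CD25 went in both directions. Of the interleukin-2 receptor family and its relatives 4 members were measured. IL7R, the interleukin-7 receptor gene, was 2.74-fold higher from a control signal of 3.94, and IL21R was 2.02-fold higher. IL4R had a difference of -0.42 and IL9R of -0.02. STAT5A and STAT5B, the transcription factor genes downstream of this receptor and of BCR-ABL1, were higher by 0.43 and 0.36 on the log2 scale, at percentiles 96.4 and 94.0 among genes of like signal. The differences of JAK1, JAK2, JAK3, TYK2 and STAT3 lay between -0.21 and 0.03. The 7 JAK and STAT genes had a median of -0.09 and a mean of 0.04, which differ in sign, and the median lay within the random range of -0.30 to 0.20. Of 17 known STAT5 target genes 1 was past 2-fold: BCL2, the gene of the apoptosis inhibitor, was 2.55-fold lower. The list had a median of -0.07 at percentile 40.8, with OSM at -0.67, CCND3, a cyclin D gene, at 0.51 and GATA1 at 0.50. Of 12 BCL2 family genes BCL2 was the 1 past 2-fold, and the list's median of 0.01 and mean of -0.14 differ in sign.

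Genes of mitosis, cholesterol synthesis and glycolysis with hypoxia were higher with CD25 shRNA, each list with its median above those of all 10000 random lists. Of 46 genes of G2 phase and mitosis, 41 had a positive difference, with a median of 0.23 (1.17-fold) and none past 2-fold. PLK1, a mitotic kinase gene, was 1.76-fold higher, CCNB2, a cyclin B gene, 1.55-fold, PSRC1 1.52-fold, and BUB1, a spindle checkpoint gene, 1.51-fold. The 33 S phase genes were not set apart, with a median of -0.06 at percentile 63.1, CCNE2 at -0.63 and MCM2 at 0.36. Among 15 glycolysis and hypoxia genes 12 had a positive difference and 3 were past 2-fold, with a median of 0.37 (1.29-fold). The 3 were BNIP3, a mitophagy receptor gene induced by hypoxia, 3.12-fold higher, NDRG1, 2.34-fold, and EGLN3, a prolyl hydroxylase gene of the hypoxia pathway, 2.15-fold. The control signal of EGLN3, 4.78, was under the level minimum. GPI, a glycolytic enzyme gene, was 1.68-fold higher. Of 17 genes of cholesterol synthesis 14 had a positive difference, with a median of 0.25. The Cajal body RNAs were higher on the same array, with a median of 0.35. INSIG1, a sterol sensor gene, was 1.88-fold higher, EBP 1.42-fold, and DHCR7, the last enzyme of the pathway, 1.40-fold.

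**Figure D2:**
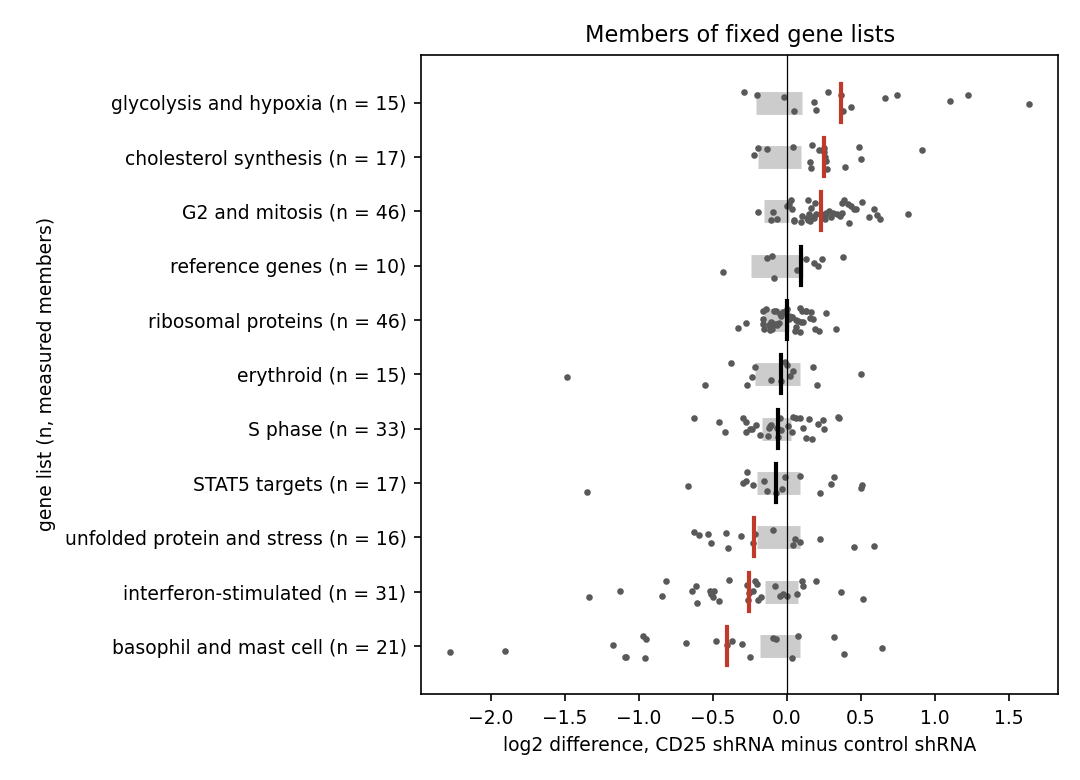
Log2 difference (CD25 shRNA minus control shRNA, x axis) of each measured member (grey points) of 11 of the fixed gene lists (y axis, with n), the list median (vertical bar, red where outside the central 95% of random lists) and the central 95% of medians of random lists matched on mean signal (grey band). The medians of the basophil and mast cell (-0.40), interferon-stimulated (-0.26) and stress (-0.22) lists lie left of their bands, and those of the mitosis (0.23), cholesterol (0.25) and glycolysis (0.37) lists lie right of theirs.

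Interferon-stimulated genes were lower with CD25 shRNA. Of 31 measured members 24 had a negative difference and 2 were at least 2-fold lower, with a median of -0.26 (1.20-fold) at percentile 0.01. XAF1, an apoptosis-linked gene, was 2.53-fold lower, EPSTI1 2.18-fold, RIGI, which encodes a sensor of viral RNA, 1.80-fold, and IFIT3 1.76-fold. The list of the unfolded protein and integrated stress response had a median of -0.22 over 16 members at percentile 1.47, with XBP1 at -0.62, ATF5 at -0.59, CTH at -0.53 and VLDLR at 0.59. This list was no longer set apart when the mean took the place of the median, at -0.15, nor when the median of neighbouring genes was subtracted, at -0.14. The cytokine and chemokine genes went both ways, with a median of -0.09 over 23 members at percentile 18.4. CCL2 was 3.30-fold higher from a low control signal of 4.50, while CXCL10 was 3.20-fold, CCL5 2.08-fold and CXCL3 1.84-fold lower.

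Small RNAs that guide modification of other RNAs in Cajal bodies were higher. All 21 measured members of the small nucleolar and Cajal body RNA list were Cajal body RNAs. Of these, 18 had a positive difference and 3 were past 2-fold, with a median of 0.35 (1.28-fold), above all random lists. SCARNA9L was 2.75-fold higher, SCARNA17 2.42-fold and SCARNA10 2.06-fold. As these RNAs carry no long poly(A) tail, their yield can depend on RNA extraction and labelling, and they were higher on the same array as the lists above. Ribosomal protein genes and commonly used reference genes had medians of 0.00 over 46 members and 0.10 over 10 members, at percentiles 94.8 and 97.0. The microRNA list, taken by symbol, had a median of -0.03 over 426 members, of which 4 were past 2-fold higher and 10 lower; the 10 are the 9 microRNA genes counted above and MIR181A1HG, a long non-coding host gene whose symbol starts alike, named after its value was seen. MIR4266 was 3.90-fold higher from a low control signal of 3.71, with differences of 1.46 and 1.96 in its probe sets. MIR29B2 was 3.06-fold lower, with a low signal of 3.45 with CD25 shRNA, and MIR181B1 2.75-fold lower. The array does not separate precursors from longer host transcripts.

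The remaining lists were not set apart with the settings used here, though some were under alternatives. Genes of the p53 response had a median of -0.20 over 14 members, with 12 negative, at percentile 3.29, and TP53INP1 was 1.89-fold lower. Output and feedback genes of the ERK pathway had a median of -0.19 over 13 members at percentile 3.25, and a mean of -0.06. Without a level minimum they were set apart at -0.24 (percentile 0.68), although DUSP6, a phosphatase gene of that pathway, was 1.72-fold higher. Immediate early genes had a median of 0.06 over 19 members at percentile 95.6, with JUN 2.04-fold higher and EGR3 at 0.54. Adhesion genes had a median of -0.13 over 11 members, with ICAM1 1.77-fold lower. Cytosolic heat shock genes, CDK inhibitors and drug targets of CML had medians of -0.07, -0.08 and -0.03 over 10, 5 and 14 members. HSPB1 was at 0.62, HSPA1A at -0.60 and RBL1 at -0.19. Of the drug targets 7 were positive and 7 negative, with KIT at -1.17, PLK1 at 0.82 and LYN at -0.45, KIT and PLK1 being members of lists above. For antigen presentation only B2M and TAPBP were measured, at -0.10 and -0.08. The histone list held H1-10-AS1 alone, an antisense transcript and not a histone mRNA, at 0.00, and 0 mitochondrial mRNAs were named. In all, 7 of 27 evaluated lists were set apart, 4 higher and 3 lower, where unrelated genes would give 1.35. The other 5 lists had fewer than 5 measured members.

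Differences were unevenly spread over the chromosomes. The genes of 7 of 23 chromosomes had medians outside the central 95% of random gene lists, where unrelated genes would give 1.15. The furthest was chromosome 14, where 237 of 350 genes had a negative difference and the median was -0.15. The size of this median depended on the level minimum: it was -0.24 at a minimum of 7 and -0.08 without one. Chromosomes 8, 13, 3 and 19 followed on the lower side, at -0.11, -0.09, -0.08 and -0.06, and chromosome 15 had a median of 0.04. Chromosome 6, at -0.01, lay above its random lists, but its sign flips when the arrays are centred, quantile normalized or fitted by loess, and it lay within the random range under 6 of 11 alternatives. Among 304 windows of 35 consecutive genes, 10 had medians below the -0.25 that bounds shuffled gene orders and 0 lay above the upper bound. Of the 10, 3 were on chromosome 14, 2 each on chromosomes 3, 8 and 19, and 1 on chromosome 1. The lowest outside chromosome 14, from ZNF616 to MBOAT7 on chromosome 19, had a median of -0.33. On chromosome 14 the lowest medians were those of 2 adjoining windows, or 70 consecutive named genes from ARF6 to MAP3K9, a block chosen after the values were seen, of which 61 had a negative difference, with a median of -0.43 and quartiles of -0.65 and -0.16. The other 280 genes of the chromosome had a median of -0.09, and their window from MAFIP to HOMEZ one of -0.26.

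**Figure D3:**
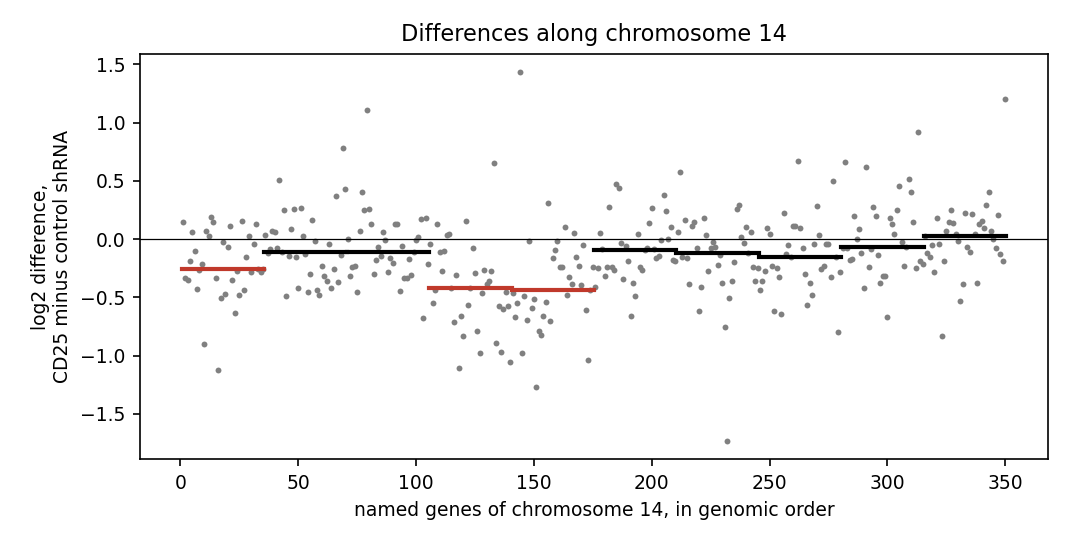
Log2 difference (CD25 shRNA minus control shRNA, y axis) of the 350 analysed genes of chromosome 14 in genomic order (x axis, gene number); horizontal bars are medians of 35 consecutive genes, red where below the range of shuffled gene orders over all chromosomes. The lowest bars, at -0.42 and -0.44, adjoin each other.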

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

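The counts of genes past 2-fold (112 higher, 72 lower) depended on the size rule and on low signals. They were 409 and 417 with a 1.5-fold rule, 29 and 10 with a 3-fold rule, 53 and 46 among genes with a log2 signal of 7 or more on at least 1 array, and 465 and 506 over all probe sets, named or not. With the 1.5-fold rule the counts were nearly level, with slightly more lower. Over all probe sets the turn towards lower signals came from the unnamed ones, of which 341 were higher and 424 lower. Under the other alternatives run the counts stayed within 1.5 times, from 79 to 130 higher and from 58 to 92 lower. The median of all genes, -0.03 as reported, was -0.025 after centring, -0.0029 after quantile normalization and -0.0013 after loess. The differences of the 132 named genes moved by at most 0.25 under these rescalings and with the mean of a gene's probe sets. The number of lists set apart (7) ranged from 6 to 10, and 6 of these 7 lists were set apart on the same side under every alternative run on them, the exception being the stress response list described above. Of the lists not set apart as reported, that of the ERK pathway was set apart in 4 of 13 alternatives, megakaryocyte genes in 3 of 12, p53 response, immediate early and CML surface genes in 2 of 13 each, adhesion (-0.23) and cytokine genes (-0.31) in 1 of 13 each and microRNA genes in 1 of 12. Sizes were less stable than sides: 128 of 597 alternative values of list and chromosome summaries moved by more than the spread of random lists (about 1 SD), among them the basophil and mast cell median (-0.95 to -0.39) and that of the Cajal body RNAs (0.35 to 0.63). The number of chromosomes set apart (7) ranged from 6 to 9. Chromosomes 3, 8, 13, 14 and 15 were set apart under all 11 alternatives and chromosome 19 under 9 of 11, while the median of chromosome 14 ranged from -0.24 to -0.08. The median of chromosome 6 turned positive with centring (0.000581), quantile normalization (0.00827) and loess (0.0127), and its mean was 0.0083. The median of all genes rose under each of these rescalings too, as given above, so the turn in sign goes with that shared shift. Subtracting neighbouring genes and restricting lists to protein-coding genes were alternatives chosen after seeing the data. No alternative could be run for IL2RA, which no named probe set carried. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. Without replicates or detection calls, differences at low signals are the least reliable.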

Other observations

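In this part the tests of intensity-dependent normalization, of a uniform difference of chromosome 14, of DAZ probes and of the germline list with the genes of its pattern included, and the genes of the next paragraph, were chosen only after the result was seen. The subtraction of neighbouring genes was also added after the largest differences had been seen.

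Further genes below control with CD25 shRNA were these. TRAF5, a signal adaptor of the TNF receptor family, was 2.58-fold lower, IKZF2, a transcription factor gene of the Ikaros family, had a difference of -1.32, the receptor gene GPR174 was 2.45-fold lower, and the membrane adaptor genes PAG1 and LAX1 were 2.34-fold and 2.26-fold lower. The signal of PAG1 with CD25 shRNA, 4.97, was under the level minimum, so the size of its fold is uncertain. SGK1, a kinase gene induced by glucocorticoids, was 2.77-fold lower and PTGS2, the gene of cyclooxygenase 2, 2.24-fold lower. On the higher side CTSE, which encodes the aspartic protease cathepsin E, was 3.73-fold higher from a log2 signal of 9.51. RRAGD, a GTPase gene of the nutrient-sensing pathway at lysosomes, was 3.97-fold higher. Its control signal, 5.04, was close to the level minimum, so the size of that fold is uncertain. The metallothionein gene MT1G was 3.15-fold higher and CYSLTR2, a cysteinyl leukotriene receptor gene, 2.87-fold.

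Probe sets without a gene name here held further differences past 2-fold. Of 18288 at the level minimum, 341 were at least 2-fold higher and 424 at least 2-fold lower, or 4.18% against 1.68% of the named genes. The probe sets with the identifiers 17079432 and 17104663 had log2 signals of 6.38 and 6.40 with CD25 shRNA against 1.91 and 2.21 with control shRNA. Those with the identifiers 16769755 and 16855164 had 2.30 and 1.94 with CD25 shRNA against 6.17 and 5.47 with control shRNA. The lower signal of each lay near the lowest values of the arrays and under the level minimum of 5, so the size of these differences is uncertain.

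Genes of chromosome 14 were lower as a block, and a candidate explanation is a copy number difference of part of that chromosome between the cultures. The medians of 10 windows of 35 consecutive genes spanned 0.47, beyond the 0.31 that bounds shuffled gene orders. This argues against a log2 difference equal in all genes of the chromosome as the whole cause. The shuffles were not matched on signal, and genes of low signal may show less of a copy number difference. Mean control signals were 8.19 and 7.54 in the block's windows and 6.43 and 6.58 in the last 2 windows. Block genes below the block's median signal still had a median of -0.36. The span therefore does not exclude a copy number difference of the whole chromosome. The test first set for a whole-chromosome copy number difference did not decide: its highest window median, 0.025, was neither below the median of all genes nor above the 0.038 of shuffled orders, so such a difference in addition to the block cannot be told apart from none. Intensity-dependent normalization is argued against, since the chromosome's median was still -0.11 after a loess correction, below the -0.04 of matched random lists. The block is not the only region of this kind, since 7 of the 10 windows below shuffled orders lay on other chromosomes; no DNA was measured here, and joint regulation of neighbouring genes, which would also widen the span, was not tested.

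Basophil and mast cell genes were lower with CD25 shRNA, a group that carries CPA3, SIGLEC6, KIT and tryptase genes. Intensity-dependent normalization as the whole cause is argued against by a list median of -0.39 after the loess correction, where matched random lists reach -0.15. Copy number differences of regions wide enough to move the median of 40 neighbouring genes are argued against. After that median was subtracted the list median was -0.46, where random lists reach -0.15. A change limited to few neighbouring genes would not move the median of the neighbours, so smaller regions were not tested. Effects of the CD25 shRNA and drift of separately transduced and selected cultures, apart from CD25, cannot be told apart with 1 array per group, and RNA handling, which was not tested, also stays open beside the higher Cajal body RNAs (median 0.35). Lower expression of basophil and mast cell genes after CD25 depletion may be held as a hypothesis only, and the depletion itself was not checked at the RNA level here.

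The germline genes DAZ1, DAZ2, DAZ3, USP26, ZFP42, DSCR8 and PASD1 were higher with CD25 shRNA, PASD1 having been named after its value was seen. The differences of the 4 DAZ probe sets lay within 0.39 of each other, so separate DAZ transcripts and probes shared between near-identical copies cannot be told apart. A list of 36 other germline and cancer-testis genes had a median of -0.050 but decides nothing on a general release, since it was drawn up without the genes seen to be higher. With 9 such genes added, those above together with TEX9 and DCAF4L2, the median of the 45 was 0.060 and the mean 0.57. The 9 were at least 2-fold higher, and DAZ1, DAZ2 and DAZ3 among them count as 1 observation. As the 9 were picked for their size, adding them can only raise these values. Of the 45, 36 stayed within 2-fold and 21 were negative, while 20% were at least 2-fold higher, against 1.02% of all genes. The upper quartile was 0.36, and the median lay within the random range of -0.12 to 0.085. The 36 were drawn up without the genes seen to be higher, and the 9 were picked for being higher. These values therefore do not decide on a general release. Unnamed germline genes and those under the level minimum are not covered. A general release, a release of few genes and outgrowth of a subclone that already used these genes may each be considered and stay open.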
